A study of Mus musculus with 21 samples.

How the data were processed

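RNA from sorted mouse bone marrow HSCs was measured in 21 libraries, 3 in each of 7 groups: 12 in the treatment experiment (WT or Mx1-Cre;Atg5fl/fl, DMSO or bortezomib) and 9 in the reporter experiment. The authors deposited raw counts per gene. Per the submitters' processing notes, RNA was prepared with an RNeasy Plus Micro kit and SMART-seq2, and reads were processed with Bowtie 1.0.0, STAR 2.6.1 and HTSeq 0.7.1. The notes name the builds GRCm38.p4 and GRCh38 without saying what each was used for. The annotation release and the strand setting of the counting are not given in the sources used here. Coordinates are GRCm38. Reads were not analysed here.

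The deposited table holds counts for 47729 genes, and 0 columns had no sample. Groups were taken from the sample labels. No library was left out of the main results, and no pair of libraries within a group was a duplicate. Library totals of 15005500 to 31481691 counts put the floor of 3 counts per library between 0.0964 and 0.190 CPM. Genes with 0 counts in a group are given as a bound against that floor, and genes with 1 to 3 counts as a ratio with a counting interval of 95%. Setting zero-count members of the lists to that bound left each list median as fitted to 2 decimals, except for erythroid markers between genotypes under bortezomib (0.82 to 0.54) and in the interaction (0.01 to -0.15).

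Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 16149 (treatment) and 15375 (reporter), and libraries were scaled by TMM. Each experiment had a single quasi-likelihood fit with a mean per group. The 8 comparisons were bortezomib against DMSO in each genotype, genotype in each treatment, their interaction, and the 3 pairs of reporter groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. CPM values use TMM-scaled library sizes. In the text, rose and fell refer to calls.

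Fixed gene lists (27, of which 8 mark other cell types) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and the preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Lists needed at least 5 tested members. Medians of lists are medians of log2 fold changes. Each was also tested with an estimated correlation and with fry. Where counts are adjusted over the list alone, the correction covers only its members. Some members of other lists, such as Kit and Cd34, are expressed by HSCs.

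Groups, comparisons, tests, lists, the rule for named genes and the alternatives listed next were fixed before the data were examined. The rule gives Atg5 first. Per comparison it then takes, among called protein-coding genes with a standard symbol, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, the 8 largest rises and 8 largest falls. For the interaction it takes 5 each way without the rule on overlap. It adds up to 4 called members of each list with the smallest p, the 2 members of highest mean CPM of each list called by camera, and, where fewer than 5 genes passed, the 5 with the smallest p. Some genes it gives are not reported here. The text gives part of the largest changes and smallest p. The text names part of these list members, mostly those whose calls held when each library was left out, so calls of named members are steadier than calls at large. Alternatives were run for a part of the genes the rule gives. Of the called genes among them, 37 of 56 (bortezomib in WT), 25 of 50 (bortezomib in knockout-labelled HSCs), 53 of 54 (genotype under bortezomib) and 23 of 37 (interaction) held under every alternative.

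The alternatives were edgeR with relative log expression size factors, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, no filter on low counts, only the libraries of the groups compared, the replicate number as a block, and leaving out each library. After seeing the data, 3 more were added: offsets from splines of log2 CPM on transcript length and GC content (4 degrees of freedom each), the Xist share of Xist plus Ddx3y counts as a covariate (also with each bortezomib library left out), and leaving out the 3 libraries apart on the third component together. On simulated data of the same design (14694 to 15576 genes) the procedure recovered 4.08% (interaction) to 40.2% (genotype under bortezomib) of 2-fold changes. Of 4-fold changes it recovered 57.3% to 75%, with 1 to 7 false gene calls. Camera called 1 fixed list (genotype in DMSO) not changed as a set. This does not check its preset correlation. Figures were drawn with Python 3.11 and matplotlib 3.10.9.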

Results

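RNA was sequenced from hematopoietic stem cells (HSCs) of mouse bone marrow, sorted as CD48-negative, CD150-positive cells within the lineage-negative, Sca-1-positive, Kit-positive (LSK) fraction. The 21 SMART-seq2 libraries form 7 groups of 3. In the treatment experiment, wild-type (WT) mice and mice labelled Mx1-Cre;Atg5fl/fl (knockout) received bortezomib, a proteasome inhibitor, at 10 mg/kg, or 10% DMSO, by retro-orbital injection 48 h and 24 h before analysis. Atg5 is required to conjugate LC3 to membranes during autophagy. In the reporter experiment, HSCs of untreated RFP-EGFP-LC3 mice were sorted by fluorescence into RFP single positive, RFP and GFP double positive, and double negative cells. EGFP is quenched in acidic lysosomes and RFP is not, so the ratio of the colours is used as a measure of autophagic flux. Libraries held 16095 to 18899 detected genes. Values below are mean counts scaled to library size (CPM) ± SD with n = 3 libraries per group. The labels do not give separate animals, so each p-value measures the spread between these samples. Sex markers (below) argue against a purely technical spread, except in knockout-labelled DMSO.

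Atg5 (ENSMUSG00000038160.6, chromosome 10, 44268358 to 44364291, GRCm38) was examined before any other gene. It stood at 56.5 ± 17.4 CPM in WT DMSO, 103 ± 31.6 in WT bortezomib, 112 ± 3.77 in knockout-labelled DMSO and 111 ± 27.2 in knockout-labelled bortezomib libraries. Single libraries ranged from 39.9 CPM in WT DMSO 2 to 142.5 CPM in knockout-labelled bortezomib 3. The reporter groups held 102 ± 17.3 (single positive), 111 ± 21.2 (double positive) and 112 ± 27.7 CPM (double negative). Atg5 counts were thus not lower in the knockout-labelled libraries. A count over the whole gene cannot isolate a deleted part of it, so it checks nothing about these labels, and the libraries are called knockout-labelled throughout. Atg5 rose in WT bortezomib against WT DMSO (log2 fold change 0.86, SE 0.25, edgeR adjusted p = 0.0302), a call that ended with the Xist covariate added after seeing the data (adjusted p = 0.0575) and without WT DMSO 1 (adjusted p = 0.0997), WT DMSO 2 (0.147), WT bortezomib 1 (0.0880) or WT bortezomib 3 (0.129).

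Markers of sex differed between libraries of the same group. Xist made up 99.2% and 98.6% of Xist plus Ddx3y counts in WT DMSO 1 and 2 but 60.0% in WT DMSO 3, and 46.4%, 31.8% and 90.3% in WT bortezomib 1, 2 and 3. The share was at most 0.987% in all knockout-labelled DMSO libraries, 100% in knockout-labelled bortezomib 1, and 0 and 3.51% in knockout-labelled bortezomib 2 and 3. In the reporter experiment the replicates numbered 2 were mostly Xist-expressing (99.9%, 97.4% and 88.1%) and the others were at most 10.2%. On the third principal component WT DMSO 3, WT bortezomib 3 and knockout-labelled bortezomib 3 stood apart (-65.2, -38.0 and -47.6), all numbered 3. Among the reporter libraries, double negative 1 stood apart on the first component (118), double positive 2 on the second (95.3) and double positive 1 on the third (-95.6).

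**Figure D1:**
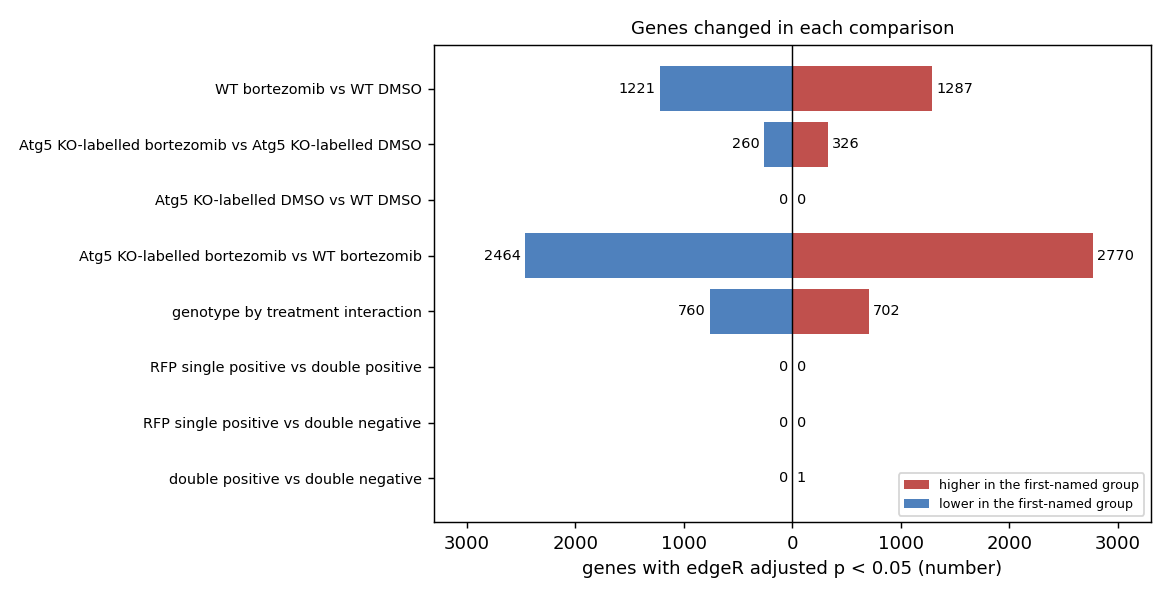
Number of genes with an edgeR adjusted p under 0.05 in each of the 8 comparisons (horizontal axis), higher in the first-named group to the right and lower to the left. The comparison between genotypes under bortezomib has the longest bars (2770 and 2464), and 3 comparisons show 0 genes on both sides.

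WT bortezomib was compared with WT DMSO to ask how HSCs respond to inhibition of the proteasome. Genes of the proteasome itself rose: of 36 subunit and assembly genes, 31 rose and 0 fell, and 33 rose adjusted over the list alone. Their median was 0.93 (camera adjusted p = 2.27e-19, adjusted p = 0.331 with an estimated correlation). Psmb3 (ENSMUSG00000069744.7, chromosome 11, 97703399 to 97713500) rose from 199.6 ± 28.2 to 492 ± 45.7 CPM (log2 fold change 1.30, SE 0.18, edgeR adjusted p = 0.00193), and Psma7 rose from 669 ± 208 to 1619 ± 106 CPM (log2 fold change 1.27, adjusted p = 0.00487). Cell cycle genes also rose, 21 of 36 over all genes and 24 adjusted over the list alone. Their median was 0.82 (camera adjusted p = 2.14e-09, adjusted p = 0.565 with an estimated correlation). Among them the mitotic kinase Cdk1 rose from 117 ± 19.9 to 273 ± 45.2 CPM and the survivin gene Birc5 from 80.2 ± 14.5 to 208 ± 71.2 CPM. HSC identity genes fell, 19 of 33 over all genes and 23 adjusted over the list alone. Their median was -0.67 (camera adjusted p = 6.64e-10, adjusted p = 0.157 with an estimated correlation). Tek, the angiopoietin receptor (ENSMUSG00000006386.15, chromosome 4, 94739289 to 94874976), fell from 74.5 ± 17.2 to 28.5 ± 4.20 CPM (log2 fold change -1.39, SE 0.19, edgeR adjusted p = 0.00193), Angpt1 from 747 ± 115 to 327 ± 4.29 CPM, and Kit, whose protein is part of the sort, from 894 ± 172 to 408 ± 69.6 CPM.

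Nuclear genes of oxidative phosphorylation rose in WT bortezomib, 39 of 45 over all genes, with 42 higher and 1 lower adjusted over the list alone. Their median was 0.82 (camera adjusted p = 6.85e-17, adjusted p = 0.565 with an estimated correlation). Cycs, which encodes cytochrome c, rose from 64.0 ± 12.5 to 211 ± 26.8 CPM (log2 fold change 1.72, SE 0.28, edgeR adjusted p = 0.00327) and Cox5a from 132 ± 20.6 to 328 ± 51.5 CPM. Of 76 cytosolic ribosomal protein genes, 20 rose, or 30 adjusted over the list alone (median 0.53, camera adjusted p = 7.67e-13, adjusted p = 0.642 with an estimated correlation), Rpl27 among them (from 343 ± 86.8 to 742 ± 36.4 CPM). Transcripts of the mitochondrial genome moved the other way: 3 of 13 fell, also 3 adjusted over the list alone. Their median was -0.44 (camera adjusted p = 0.0210, adjusted p = 0.644 with an estimated correlation). mt-Nd6 fell from 235 ± 40.7 to 108 ± 25.5 CPM. The mitochondrial call ended without WT DMSO 3 (median -0.28, adjusted p = 0.219), WT bortezomib 1 (0.0662) or WT bortezomib 2 (0.0789). With offsets for transcript length and GC content, added after seeing the data, the oxidative phosphorylation median was 0.43 (adjusted p = 0.00704) and the ribosomal call ended (median 0.20, camera direction down, adjusted p = 0.352). The mitochondrial median was then -1.05 (adjusted p = 8.95e-07), mt-Nd6 -2.01 and Rpl27 0.67. Without the 3 libraries apart on the third component, a test also added later, the mitochondrial (adjusted p = 0.0932) and ER chaperone calls (0.0932) ended and the ribosomal median was 0.84.

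Genes of the endoplasmic reticulum (ER) chaperone list were called higher by camera, with 8 of 28 higher and 1 lower, or 12 and 1 adjusted over the list alone. Their median was 0.26 (camera adjusted p = 0.00142, adjusted p = 0.565 with an estimated correlation). Manf, an ER-resident stress protein, rose from 116 ± 24.8 to 268 ± 27.9 CPM. Interferon-stimulated genes fell, 12 of 34 over all genes, with 1 higher and 16 lower adjusted over the list alone. Their median was -0.58 (camera adjusted p = 0.000491, adjusted p = 0.642 with an estimated correlation). The antiviral gene Rsad2 fell from 49.0 ± 9.56 to 18.2 ± 5.03 CPM and Ddx58, which encodes RIG-I, from 104 ± 19.2 to 49.6 ± 3.40 CPM. NF-kB targets fell too, 6 of 19, or 11 adjusted over the list alone. Their median was -0.76 (camera adjusted p = 0.000165, adjusted p = 0.565 with an estimated correlation). Birc3 fell from 42.6 ± 3.16 to 20.8 ± 1.03 CPM, with an adjusted p of 0.0532 without WT bortezomib 1.

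No other list passed camera in this comparison, with adjusted p from 0.0687 to 0.940. In core autophagy 1 of 31 genes rose and 9 fell (1 and 11 adjusted over the list alone), including a rise of Vmp1 (from 161 ± 35.9 to 299.6 ± 1.67 CPM) and a fall of Rb1cc1 (from 75.3 ± 21.0 to 31.7 ± 4.35 CPM). Of 23 autophagy receptors and aggresome factors 1 rose and 3 fell (1 and 3 adjusted over the list alone). Phb2, a mitophagy receptor, rose from 229 ± 15.04 to 445 ± 28.6 CPM and Calcoco1 fell from 46.7 ± 16.9 to 14.8 ± 3.21 CPM. Sqstm1, the p62 receptor that links ubiquitinated proteins to LC3 (ENSMUSG00000015837.15, chromosome 11, 50199366 to 50210827), stood at 228 ± 49.3 against 322 ± 53.1 CPM (edgeR adjusted p = 0.174). Heat shock and cytosolic chaperones had 6 of 28 genes higher and 1 lower (6 and 2 adjusted over the list alone), among them Cacybp, which rose from 252 ± 41.2 to 554 ± 23.0 CPM. Counts were 6 higher and 3 lower of 24 for ATF4 targets (7 and 3 adjusted over the list alone), where Trib3 fell from 47.4 ± 10.7 to 20.5 ± 5.37 CPM. They were 2 and 3 of 24 for NRF2 targets (2 and 3 adjusted over the list alone), where the redox protein gene Txn1 rose from 645 ± 191 to 1512 ± 226 CPM (1.23, but 0.80 with length and GC offsets) and Osgin1 fell from 40.1 ± 4.80 to 11.2 ± 1.79 CPM. Lysosomal genes gave 1 higher and 6 lower of 38 (1 and 7 adjusted over the list alone). Glycolysis gave 4 and 1 of 18 (4 and 1 adjusted over the list alone), including a rise of Ldha from 1339 ± 155 to 2911 ± 227 CPM. P53 targets gave 2 and 4 of 22 (4 and 4), immediate early genes 1 and 3 of 20 (1 and 3) and cholesterol synthesis 0 and 1 of 23 (0 and 1).

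The 8 marker lists of other cell types, also not called, had medians of 0.25 (erythroid), 0.23 (neutrophil), 0.018 (megakaryocyte), -2.32 (B cell), 0.17 (T and NK cell), 0.038 (monocyte and macrophage), -0.15 (progenitor) and -1.23 (endothelial and stromal). Means had the opposite sign for the erythroid (-0.37), megakaryocyte (-0.046), T and NK cell (-0.038) and p53 lists (-0.13 against a median of 0.066). Single markers that changed included Cd48, whose protein the sort excludes, which rose from 11.2 ± 1.20 to 39.8 ± 12.7 CPM (log2 fold change 1.83, SE 0.38, edgeR adjusted p = 0.00723). Others were the macrophage gene Cd68, which rose from 21.3 ± 2.57 to 53.9 ± 8.43 CPM, and the megakaryocyte gene Mmrn1, which fell from 503.6 ± 85.2 to 258 ± 6.77 CPM.

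Ranked genes here and below have a standard symbol and at least 5 CPM in the higher group, and for largest rises and falls no overlap between libraries. The largest rise in WT bortezomib was in Fbxo2, a ubiquitin ligase subunit that binds glycoproteins (ENSMUSG00000041556.8, chromosome 4, 148160621 to 148166424; from 0.266 ± 0.255 to 9.78 ± 2.89 CPM, log2 fold change 5.20, SE 0.78, edgeR adjusted p = 0.00237). Next were Clec10a (from 0.458 ± 0.382 to 5.32 ± 3.30 CPM), the fatty acid binding protein Fabp4 (from 1.29 ± 0.957 to 13.3 ± 10.3 CPM) and S100a4 (from 9.94 ± 3.67 to 69.1 ± 32.6 CPM). The largest falls were in Thbs1 (from 9.73 ± 6.46 to 0.652 ± 0.558 CPM), Shisa9 (from 5.20 ± 1.83 to 0.436 ± 0.611 CPM), Slc22a21 (from 5.90 ± 3.45 to 0.522 ± 0.0734 CPM) and Lama4 (from 5.12 ± 0.364 to 0.466 ± 0.517 CPM). Calls ended without WT DMSO 1 for Thbs1 and Shisa9 (adjusted p = 0.104 and 0.119), WT DMSO 2 for Thbs1 and Shisa9 (0.0571 and 0.140), WT bortezomib 1 for Thbs1, Shisa9 and Slc22a21 (0.0977, 0.165 and 0.0548), WT bortezomib 2 for Thbs1 (0.0790) and WT bortezomib 3 for Shisa9 (0.0869). Without WT bortezomib 2 the fitted fold of Shisa9, near 0 in a group, moved by over 1.5 times (adjusted p = 0.0265). Shisa9 also lost its call with length and GC offsets (0.0530) and the Xist covariate (0.0634).

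In total 2508 of 16149 genes tested passed an edgeR adjusted p of 0.05, 1287 higher and 1221 lower, and 4933 had an unadjusted p under 0.05. Leaving libraries out gave up to 2762 (without WT DMSO 3) and, among lower counts, 983 without WT DMSO 1, 731 without WT DMSO 2, 588 without WT bortezomib 1 and 1325 without WT bortezomib 2. Limma voom gave 6234, the Xist covariate 1629 and the omission of the 3 libraries 3961.

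**Figure D2:**
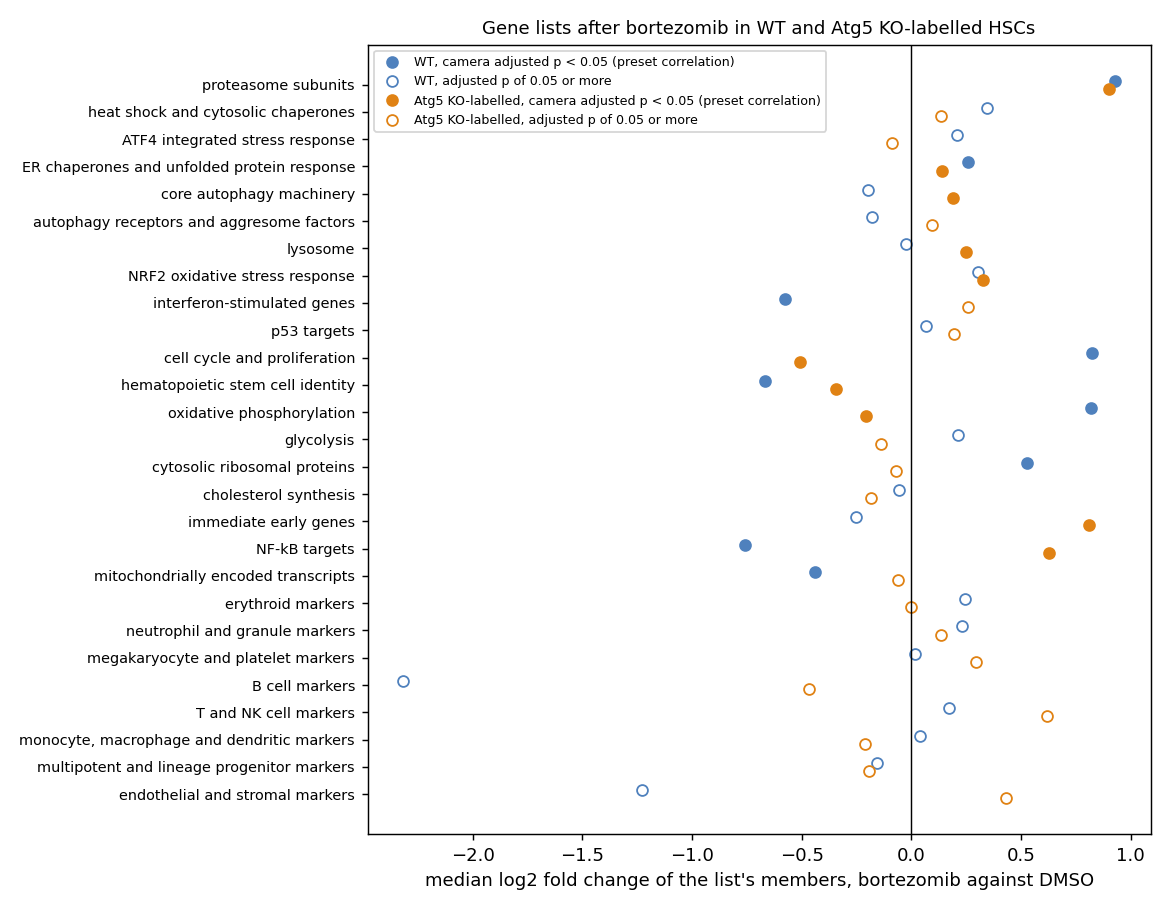
Median log2 fold change of each of the 27 gene lists after bortezomib against DMSO (horizontal axis), in WT (blue) and knockout-labelled HSCs (orange), with filled circles where the camera adjusted p with the preset correlation is under 0.05. Proteasome genes lie at 0.93 and 0.90, and oxidative phosphorylation at 0.82 and -0.20.

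In knockout-labelled HSCs the same comparison of bortezomib with DMSO asks how the response runs where Atg5 is targeted. Proteasome genes rose, 26 of 36 over all genes, with 31 higher and 1 lower adjusted over the list alone. Their median was 0.90 (camera adjusted p = 6.16e-26, adjusted p = 0.236 with an estimated correlation). Psmc2 (ENSMUSG00000028932.7, chromosome 5, 21785283 to 21803787) rose from 145 ± 23.2 to 417 ± 24.9 CPM (log2 fold change 1.53, SE 0.16, edgeR adjusted p = 0.000124) and Psmd1 from 234 ± 46.9 to 623 ± 70.5 CPM. The p62 gene Sqstm1 rose from 330.4 ± 54.6 to 1180.5 ± 423 CPM (log2 fold change 1.84, SE 0.25, edgeR adjusted p = 0.000861). NRF2 targets rose, 6 of 24 with 1 lower, or 9 and 1 adjusted over the list alone. Their median was 0.33 (camera adjusted p = 0.000265, adjusted p = 0.236 with an estimated correlation). Malic enzyme Me1 (ENSMUSG00000032418.15, chromosome 9, 86581371 to 86695953) rose from 6.97 ± 1.40 to 44.4 ± 1.72 CPM (log2 fold change 2.67, SE 0.26, edgeR adjusted p = 0.000105), sulfiredoxin Srxn1 from 39.3 ± 6.03 to 125 ± 13.6 CPM and Nqo1 from 22.6 ± 4.11 to 60.7 ± 13.1 CPM.

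Immediate early genes rose, 6 of 20 over all genes and 9 adjusted over the list alone. Their median was 0.81 (camera adjusted p = 2.44e-06, adjusted p = 0.236 with an estimated correlation), with Socs3 rising from 41.2 ± 20.8 to 225 ± 47.4 CPM and Egr1 from 26.3 ± 7.18 to 109.7 ± 58.2 CPM. NF-kB targets rose, 5 of 19 and 6 adjusted over the list alone. Their median was 0.63 (camera adjusted p = 0.000128, adjusted p = 0.467 with an estimated correlation). Lysosomal genes rose, 4 of 38, with 11 higher and 2 lower adjusted over the list alone. Their median was 0.25 (camera adjusted p = 6.08e-05, adjusted p = 0.416 with an estimated correlation). Atp6v1h, a subunit of the proton pump, rose from 108 ± 10.6 to 215 ± 11.9 CPM. Core autophagy genes rose, 4 of 31 in either adjustment, over all genes and adjusted over the list alone. Their median was 0.19 (camera adjusted p = 0.00268, adjusted p = 0.236 with an estimated correlation). ER chaperone genes gave 3 of 28 higher, or 4 adjusted over the list alone. Their median was 0.14 (camera adjusted p = 0.0161, adjusted p = 0.502 with an estimated correlation). Among genes of these lists, Cxcl10 rose from 8.47 ± 2.09 to 29.5 ± 11.2 CPM and Vmp1 from 129 ± 22.3 to 232 ± 26.4 CPM. Calls ended without knockout-labelled DMSO 1 for Cxcl10 (adjusted p = 0.0543), DMSO 2 for Cxcl10 and Vmp1 (0.0935 and 0.0606), DMSO 3 for Vmp1 and the ER list (0.0667 and 0.252), bortezomib 2 for Cxcl10 and Vmp1 (0.0835 and 0.0559), and bortezomib 3 for the ER list (0.0750). List medians moved without bortezomib 2 for immediate early genes (0.47), NF-kB targets (0.41) and core autophagy (0.11). NF-kB targets gave 0.96 without DMSO 3 and 0.94 without bortezomib 3, and the ER list 0.25 without DMSO 1 and 0.059 without DMSO 3.

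Cell cycle genes fell in the knockout-labelled libraries, 7 of 36, or 15 adjusted over the list alone. Their median was -0.51 (camera adjusted p = 1.34e-06, adjusted p = 0.489 with an estimated correlation), with medians of -0.33 without DMSO 1 and -0.83 without bortezomib 1. Mcm5, part of the replicative helicase, fell from 315 ± 106 to 133 ± 34.4 CPM, with an adjusted p of 0.0579 without DMSO 2. HSC identity genes gave 3 higher and 5 lower of 33, or 4 and 7 adjusted over the list alone. Their median was -0.34 (camera adjusted p = 0.0347, adjusted p = 0.489 with an estimated correlation). Angpt1 fell from 553 ± 74.3 to 282 ± 4.44 CPM and Hlf from 449.8 ± 122 to 209.6 ± 18.8 CPM, while Sult1a1 rose from 22.8 ± 7.27 to 64.6 ± 23.7 CPM (adjusted p = 0.0682 without DMSO 2 and 0.0603 without bortezomib 2). Oxidative phosphorylation was called lower with 0 of 45 members passing, and 0 adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.00398, adjusted p = 0.715 with an estimated correlation). The HSC identity call ended without DMSO 3 (median -0.15, adjusted p = 0.157) or bortezomib 3 (-0.22 and 0.0750), and its median was -0.20 without bortezomib 2. The oxidative phosphorylation call ended without DMSO 2 (-0.087 and 0.115), bortezomib 1 (-0.084 and 0.135) or bortezomib 2 (-0.082 and 0.155), and its median was -0.46 without bortezomib 3. Without the 3 libraries the HSC identity (adjusted p = 0.108) and ER calls (0.0899) ended, and medians were -0.45 (oxidative phosphorylation) and 0.95 (NF-kB). Length and GC offsets also ended the HSC identity call (0.161).

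Lists not called by camera still held genes that changed. Heat shock and cytosolic chaperones had 4 of 28 higher and 1 lower (6 and 2 adjusted over the list alone), with camera adjusted p = 0.0657. The polyubiquitin gene Ubb rose from 899 ± 50.5 to 1593 ± 108 CPM. The cell cycle inhibitor Cdkn1a rose from 9.01 ± 1.11 to 30.6 ± 5.53 CPM and the amino acid transporter subunit Slc3a2 from 184 ± 12 to 372 ± 40.8 CPM, and the glycolytic gene Tpi1 fell from 533 ± 70.4 to 251 ± 71.5 CPM. Median and mean or test differed in sign for ATF4 targets (median -0.088, camera direction up) and neutrophil markers (median 0.14, mean -0.0011).

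The largest rise within the limits above was in Nol3, an apoptosis repressor (ENSMUSG00000014776.6, chromosome 8, 105276140 to 105281939), with 372 counts in knockout-labelled bortezomib and 0 in knockout-labelled DMSO libraries, at least 33.8-fold higher against a floor of 3 counts per library. Kif1a, a kinesin, had 2 counts in DMSO (ratio 310, 95% counting interval 85.6 to 2567). Intervals and floors cover counting error only. Fbxo2 rose from 0.2497 ± 0.388 to 25.3 ± 0.722 CPM (log2 fold change 6.79, SE 0.84, edgeR adjusted p = 0.000582), and the small heat shock protein Hspb8 (ENSMUSG00000041548.4, chromosome 5, 116408491 to 116422864), a partner of Bag3 in chaperone-assisted autophagy, rose from 3.29 ± 1.05 to 81.9 ± 6.95 CPM (log2 fold change 4.64, SE 0.47, edgeR adjusted p = 0.000105). The largest falls within them were in Gkn3 (from 7.33 ± 6.61 to 0.455 ± 0.564 CPM), Gapt (from 5.41 ± 0.874 to 0.579 ± 0.414 CPM), Syt3 (from 6.52 ± 0.611 to 0.904 ± 0.556 CPM) and Ddx4 (from 8.86 ± 6.28 to 1.23 ± 0.627 CPM). Calls ended without DMSO 2 for Gkn3 and Ddx4 (adjusted p = 0.161 and 0.0989), bortezomib 1 for both (0.0900 and 0.0624) and bortezomib 2 for Gkn3 (0.0598). They also ended with limma voom for both (0.0728 and 0.0661), the Xist covariate for Gkn3 (0.0700), and only the groups compared for Gkn3 (0.0662).

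By edgeR, 586 of 16149 genes passed, 326 higher and 260 lower, and 2691 had an unadjusted p under 0.05. The count was 303 without knockout-labelled DMSO 1, 182 without DMSO 2, 240 without bortezomib 2, 1040 without bortezomib 3 and 1902 without the 3 libraries. It was 1283 with DESeq2, 1577 with limma voom, 1085 without a filter and 318 with only the groups compared. Of the genes changed in WT and in knockout-labelled HSCs, 176 were shared, against 91.0 for independent lists. By direction, 73 were higher in both (26.0 for independent lists), 45 lower in both (19.7), 33 higher in WT and lower in knockout-labelled cells (20.7) and 25 the reverse (24.6). Across the 16149 genes, which are not independent replicates, the 2 sets of fold changes had a Pearson r of 0.031 and a Spearman rho of -0.020.

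**Figure D3:**
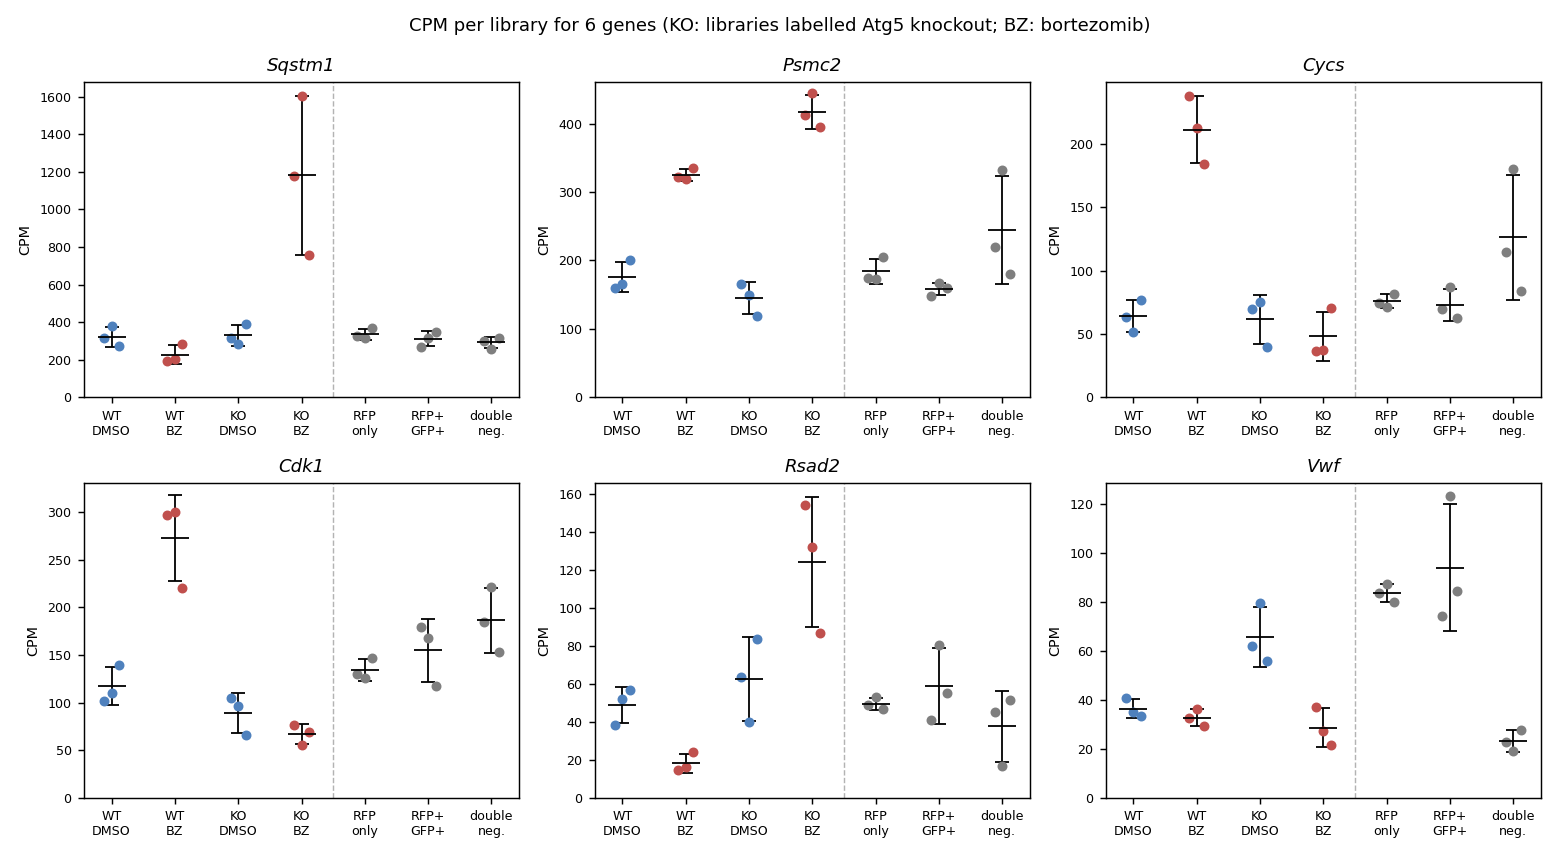
CPM per library (points) with mean and SD (bars) for Sqstm1, Psmc2, Cycs, Cdk1, Rsad2 and Vwf in all 7 groups, the treatment experiment to the left of the dashed line. Sqstm1 averages 1180.5 CPM in knockout-labelled bortezomib libraries and at most 337 CPM in any other group.

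The genotypes were compared in DMSO to ask what targeting Atg5 changes without proteasome inhibition. Progenitor markers and interferon-stimulated genes lay higher, and proteasome, ER chaperone and cholesterol synthesis genes lower, in knockout-labelled than in WT libraries by camera, with no single gene passing by edgeR. Called higher were interferon-stimulated genes (2 of 34 adjusted over the list alone, median 0.35, camera adjusted p = 0.00206, adjusted p = 0.990 with an estimated correlation). Erythroid markers (0 of 13 adjusted over the list alone, median 0.78, camera adjusted p = 0.0425, adjusted p = 0.377 with an estimated correlation) and progenitor markers (3 of 16 adjusted over the list alone, median 0.34, camera adjusted p = 0.0125, adjusted p = 0.990 with an estimated correlation) were also called higher. Those called lower were proteasome subunits (0 of 36 adjusted over the list alone, median -0.25, camera adjusted p = 0.00217, adjusted p = 0.990 with an estimated correlation). ER chaperones (6 of 28 adjusted over the list alone, median -0.26, camera adjusted p = 0.00206, adjusted p = 0.920 with an estimated correlation) and cholesterol synthesis (2 of 23 adjusted over the list alone, median -0.16, camera adjusted p = 0.0259, adjusted p = 0.377 with an estimated correlation) were lower too. Among abundant members, Plac8, a myeloid and lymphoid progenitor gene, stood at 451 ± 80.4 against 216 ± 71.8 CPM (edgeR adjusted p = 0.256), Hbb-bt at 133 ± 61.6 against 56.3 ± 12.4 (0.470) and the ER oxidoreductase Pdia3 at 638 ± 155 against 1007 ± 76.0 (0.245). Other abundant members moved little or against their list: Ifi47 (0.048), Psmb8 (-0.092), Srebf2 (0.23), Car2 (-0.32) and Cd34 (-0.046).

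Without knockout-labelled DMSO 3, 5 of these 6 calls ended: proteasome (median -0.12, adjusted p = 0.361), ER (-0.13, 0.0515), cholesterol (0.0669), erythroid (0.26, 0.248) and progenitor (0.248), and the interferon median was 0.20. Calls also ended without WT DMSO 3 for the proteasome (median -0.11, adjusted p = 0.111) and erythroid lists (0.0800), without WT DMSO 2 for the erythroid list (0.0717) and without knockout-labelled DMSO 1 for cholesterol synthesis (0.0853). Without the 3 libraries the proteasome (-0.098, 0.133) and erythroid calls (0.109) ended. The proteasome list turned with length and GC offsets (median -0.064, adjusted p = 0.248). Medians moved without WT DMSO 1 for the ER and interferon lists (-0.17 and 0.22), WT DMSO 3 and knockout-labelled DMSO 1 for progenitor markers (0.23 and 0.53) and knockout-labelled DMSO 2 for cholesterol synthesis (-0.29). Median and mean or test differed in sign for core autophagy, lysosome, immediate early, NF-kB and T and NK cell lists, whose camera adjusted p lay between 0.678 and 0.979.

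By edgeR 0 of 16149 genes passed between the genotypes in DMSO, with 1454 at an unadjusted p under 0.05; DESeq2 called 178, limma voom 114 and edgeR without a filter 189. EdgeR called 23 with only the groups compared, 15 with length and GC offsets, 2 with the Xist covariate and 40 without the 3 libraries. The smallest p within the limits for ranked genes belonged to Plxnb2, a semaphorin receptor (58.3 ± 4.09 against 24.1 ± 5.21 CPM, log2 fold change 1.27, SE 0.19, edgeR adjusted p = 0.0534). Others among the smallest were Gimap4 (51.4 ± 5.82 against 18.1 ± 2.63), Tgfbi (114 ± 36.6 against 36.8 ± 8.88) and the transcription repressor Gfi1 (58.8 ± 5.90 against 15.8 ± 8.60), with adjusted p up to 0.0664. Sqstm1 stood at 330.4 ± 54.6 against 322 ± 53.1 CPM. Xist was not called, at 0.157 to 0.633 CPM in knockout-labelled and 59.2 to 89.7 CPM in WT DMSO. The count of 0 thus missed a large difference. Without WT DMSO 3, 1 gene passed. Simulations recovered 30.9% of 2-fold and 68.8% of 4-fold changes, and camera called 1 list not changed as a set.

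Under bortezomib the genotypes were compared to ask whether targeting Atg5 changes the HSC state during proteasome inhibition. Oxidative phosphorylation, cell cycle and ribosomal protein genes were lower in knockout-labelled than in WT bortezomib libraries. Of 45 oxidative phosphorylation genes 41 fell, also 41 adjusted over the list alone (median -1.07, camera adjusted p = 9.76e-18, adjusted p = 0.404 with an estimated correlation). Cycs fell from 211 ± 26.8 to 48.1 ± 19.6 CPM (log2 fold change -2.13, SE 0.28, edgeR adjusted p = 0.000168) and Cox5a from 328 ± 51.5 to 99.9 ± 33.3 CPM. Of 36 cell cycle genes 26 fell, also 26 adjusted over the list alone (median -1.36, camera adjusted p = 2.99e-11, adjusted p = 0.404 with an estimated correlation). They include cyclin E2 (Ccne2, from 191 ± 35.6 to 30.3 ± 7.22 CPM) and Cdk1 (from 273 ± 45.2 to 67.1 ± 10.7 CPM). Of 76 ribosomal protein genes 35 fell, or 41 adjusted over the list alone (median -0.56, camera adjusted p = 2.28e-10, adjusted p = 0.583 with an estimated correlation), and Rpl5 fell from 494 ± 16.9 to 219 ± 53.8 CPM.

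Autophagy and lysosome genes were higher in the knockout-labelled bortezomib libraries. Of core autophagy genes 14 of 31 rose and 1 fell (17 and 1 adjusted over the list alone, median 0.44, camera adjusted p = 0.00154, adjusted p = 0.353 with an estimated correlation). Of receptors and aggresome factors 10 of 23 rose and 3 fell (11 and 4 adjusted over the list alone, median 0.40, camera adjusted p = 0.0441, adjusted p = 0.417 with an estimated correlation). Further, 16 of 38 lysosomal genes rose and 3 fell (18 and 4 adjusted over the list alone, median 0.37, camera adjusted p = 0.00159, adjusted p = 0.417 with an estimated correlation). Sqstm1 rose from 228 ± 49.3 to 1180.5 ± 423 CPM (log2 fold change 2.37, SE 0.25, edgeR adjusted p = 7.94e-05). The kinase gene Ulk1, which starts autophagy, rose from 26.6 ± 1.19 to 98.8 ± 41.8 CPM and acid alpha-glucosidase Gaa from 177 ± 13.1 to 420.4 ± 44.3 CPM. Phb2 fell from 445 ± 28.6 to 169.8 ± 30.5 CPM. The receptor call ended without WT bortezomib 3 (adjusted p = 0.0847) or knockout-labelled bortezomib 1 (0.0527). With length and GC offsets the core autophagy (adjusted p = 0.0748), receptor (0.201), lysosome (0.0548) and HSC identity (0.160) calls ended. Camera then put the ribosomal list in the opposite direction, up (median -0.13, adjusted p = 0.00112). The oxidative phosphorylation median was -0.67 (adjusted p = 0.0144) and Rpl5 -0.78.

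Inflammatory and signalling genes were higher as well. Interferon-stimulated genes rose, 22 of 34 with 3 lower, or 23 and 4 adjusted over the list alone. Their median was 1.32 (camera adjusted p = 2.75e-06, adjusted p = 0.417 with an estimated correlation). Rsad2 (ENSMUSG00000020641.15, chromosome 12, 26442746 to 26456452) rose from 18.2 ± 5.03 to 124 ± 34.4 CPM. NF-kB targets rose, 16 of 19 and 17 adjusted over the list alone. Their median was 1.69 (camera adjusted p = 9.80e-08, adjusted p = 0.404 with an estimated correlation), with chemokine Cxcl10 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889) rising from 1.97 ± 0.761 to 29.5 ± 11.2 CPM (log2 fold change 3.91, SE 0.42, edgeR adjusted p = 7.94e-05). Immediate early genes rose, 10 of 20 and 11 adjusted over the list alone (median 0.93, camera adjusted p = 0.000927, adjusted p = 0.404 with an estimated correlation), Socs3 from 26.1 ± 6.52 to 225 ± 47.4 CPM. HSC identity genes rose, 15 of 33 with 3 lower in both adjustments, over all genes and adjusted over the list alone (median 0.49, camera adjusted p = 0.00159, adjusted p = 0.404 with an estimated correlation), Tek from 28.5 ± 4.20 to 101 ± 14.6 CPM. ER chaperone genes went down, 10 of 28 with 4 higher in both adjustments, over all genes and adjusted over the list alone. Their median was -0.39 (camera adjusted p = 0.00652, adjusted p = 0.417 with an estimated correlation). Sdf2l1 fell from 215 ± 27.2 to 31.7 ± 13.4 CPM and Manf from 268 ± 27.9 to 98.8 ± 21.0 CPM. Cholesterol synthesis had 6 of 23 lower and 1 higher, or 7 and 1 adjusted over the list alone (median -0.34, camera adjusted p = 0.0337, adjusted p = 0.353 with an estimated correlation), a call that ended without WT bortezomib 3 (0.0519), knockout-labelled bortezomib 3 (0.0721) or the 3 libraries (0.0699).

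Proteasome genes were not called as a list (6 of 36 higher and 8 lower, 6 and 11 adjusted over the list alone, camera adjusted p = 0.138). The list passed as higher with length and GC offsets (median 0.22, adjusted p = 0.000980), and without the 3 libraries as lower (-0.56, 0.0462). Psmd3 rose from 228 ± 7.12 to 506 ± 92.5 CPM and Psmg2 fell from 141 ± 7.75 to 67.4 ± 13.5 CPM (-1.06, but -0.47 with the offsets). Among genes of other lists not called, the phosphatase subunit Ppp1r15a rose from 20.2 ± 2.43 to 95.1 ± 42.8 CPM. Osgin1 rose from 11.2 ± 1.79 to 64.7 ± 10.3 CPM, and the p53 target Bbc3, which encodes PUMA, from 10.8 ± 1.31 to 38.2 ± 7.98 CPM. Markers of other cells moved in both directions. C1qa, a complement gene of macrophages, fell from 17.7 ± 8.29 to 2.93 ± 1.23 CPM. Cd48 fell from 39.8 ± 12.7 to 8.86 ± 5.41 CPM, while Satb1 rose from 5.54 ± 1.53 to 19.7 ± 2.18 CPM and Ccl5 from 0.454 ± 0.568 to 14.97 ± 6.76 CPM. Itgb3 rose from 23.3 ± 3.57 to 99.95 ± 37.5 CPM and the platelet gene Ppbp fell from 5.96 ± 2.04 to 1.18 ± 0.360 CPM (-2.33, but -1.51 with the offsets). The stromal genes Sparc and Pdgfrb rose from 2.54 ± 0.294 to 16.8 ± 6.76 CPM and from 6.11 ± 2.69 to 41.7 ± 11.7 CPM. Median and mean or test differed in sign for heat shock, ATF4 and T and NK cell lists.

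Within the same limits the largest differences above WT bortezomib were in Trnp1 (354 against 2 counts, ratio 161, 95% counting interval 44.1 to 1331), Ccl5, Serpina3i (from 0.464 ± 0.531 to 14.5 ± 8.98 CPM) and Fam46c (from 1.33 ± 1.40 to 38.5 ± 23.1 CPM). Further rises were in the interleukin 10 receptor gene Il10ra (from 2.604 ± 1.80 to 75.4 ± 28.8 CPM) and Pcdhb16 (5.67 ± 1.38 against 0.191 ± 0.289 CPM). Among the largest below it were Bcat1 (from 7.70 ± 4.84 to 0.411 ± 0.408 CPM), the eotaxin receptor Ccr3 (0.711 ± 1.07 against 12.9 ± 1.74), Rad51c (from 6.06 ± 1.33 to 0.684 ± 0.749 CPM) and Hbb-bt (from 169.6 ± 20.4 to 22.6 ± 21.9 CPM). Trnp1 lost its call without knockout-labelled bortezomib 2 (adjusted p = 0.0764). Fitted folds of genes near 0 in a group moved by over 1.5 times without WT bortezomib 1 (Pcdhb16, adjusted p = 0.000807) and knockout-labelled bortezomib 3 (Ccr3, 0.000198). By edgeR 5234 of 16149 genes passed, 2770 higher and 2464 lower, with 6797 at an unadjusted p under 0.05. The Xist share was 46.4%, 31.8% and 90.3% in the WT and 100%, 0 and 3.51% in the knockout-labelled libraries.

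The difference between the bortezomib effects of the genotypes was tested as an interaction. The effect of bortezomib was more positive in knockout-labelled HSCs for Sqstm1 (interaction log2 fold change 2.34, SE 0.34, edgeR adjusted p = 0.00384), Me1 (2.76, adjusted p = 0.00280) and Klf6 (1.98, adjusted p = 0.00230), and more negative for Cycs (-2.08, adjusted p = 0.00876), Mcm5 (-2.14, adjusted p = 0.00494) and E2f1 (-2.01, adjusted p = 0.00494). Proteasome genes gave 3 of 36 higher and 2 lower, or 4 and 2 adjusted over the list alone, with a median of -0.021, a mean of 0.021 and a camera adjusted p of 0.917. Among the largest differences, Fam46c stood at 38.5 ± 23.1 CPM in knockout-labelled bortezomib, 4.35 ± 0.798 in knockout-labelled DMSO, 1.33 ± 1.40 in WT bortezomib and 5.47 ± 1.499 in WT DMSO (log2 fold change 5.17, SE 0.86, edgeR adjusted p = 0.00574). Hbb-bt stood at 22.6 ± 21.9, 133 ± 61.6, 169.6 ± 20.4 and 56.3 ± 12.4 CPM in the same order (log2 fold change -4.14, SE 0.70, edgeR adjusted p = 0.00637) and Sdc1 at 3.84 ± 2.06, 20.7 ± 6.84, 27.5 ± 1.60 and 13.4 ± 1.96 CPM (log2 fold change -3.46, SE 0.47, edgeR adjusted p = 0.00280).

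Among lists with a more negative effect, cell cycle genes passed in 20 of 36 cases, or 27 adjusted over the list alone (median -1.49, camera adjusted p = 7.32e-14, adjusted p = 0.389 with an estimated correlation). Oxidative phosphorylation passed in 26 of 45, or 40 adjusted over the list alone (median -0.96, camera adjusted p = 1.30e-16, adjusted p = 0.389 with an estimated correlation). Ribosomal proteins passed in 5 of 76, or 21 adjusted over the list alone (median -0.60, camera adjusted p = 8.56e-11, adjusted p = 0.588 with an estimated correlation). Glycolysis genes were lower in 6 of 18, with 1 higher and 6 lower adjusted over the list alone (median -0.18, camera adjusted p = 0.0449, adjusted p = 0.588 with an estimated correlation). Among lists with a more positive effect, NF-kB targets passed in 7 of 19 cases, or 13 adjusted over the list alone (median 1.46, camera adjusted p = 9.64e-08, adjusted p = 0.389 with an estimated correlation). Immediate early genes passed in 6 of 20, or 8 adjusted over the list alone (median 1.30, camera adjusted p = 0.000326, adjusted p = 0.389 with an estimated correlation). Interferon-stimulated genes passed in 10 of 34, with 14 higher and 1 lower adjusted over the list alone (median 0.85, camera adjusted p = 0.000501, adjusted p = 0.588 with an estimated correlation). Core autophagy passed in 7 of 31, or 11 adjusted over the list alone (median 0.42, camera adjusted p = 0.000501, adjusted p = 0.389 with an estimated correlation). Lysosomal genes were higher in 6 and lower in 1 of 38, or 7 and 1 adjusted over the list alone (median 0.40, camera adjusted p = 0.000501, adjusted p = 0.476 with an estimated correlation). HSC identity genes were higher in 6 and lower in 1 of 33, or 8 and 2 adjusted over the list alone (median 0.47, camera adjusted p = 0.000530, adjusted p = 0.389 with an estimated correlation). Endothelial and stromal markers passed in 1 of 8, or 3 adjusted over the list alone (median 2.33, camera adjusted p = 0.0449, adjusted p = 0.462 with an estimated correlation).

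The core autophagy median was 0.23 without knockout-labelled bortezomib 2. Without the 3 libraries the glycolysis call ended (adjusted p = 0.285), and medians were -1.55 (oxidative phosphorylation) and -1.02 (ribosomal). Glycolysis also lost its call without WT DMSO 3 (median -0.048, adjusted p = 0.216), WT bortezomib 1 (0.0591), WT bortezomib 3 (0.0772), knockout-labelled DMSO 1 (0.101) or bortezomib 2 (0.104), and its median was -0.40 without WT DMSO 1 and -0.37 without knockout-labelled bortezomib 1. The endothelial call ended without WT DMSO 2 (0.143), WT bortezomib 1 (0.0591), 2 (0.0634) or 3 (0.0626), knockout-labelled DMSO 1 (0.134), bortezomib 1 (0.0518) or bortezomib 3 (0.0876).

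By edgeR the interaction passed for 1462 of 16149 genes, 702 positive and 760 negative, with 4178 at an unadjusted p under 0.05. The count fell without WT DMSO 1 (741), WT DMSO 2 (416), WT bortezomib 1 (397), WT bortezomib 2 (681), knockout-labelled DMSO 1 (613), DMSO 2 (352), bortezomib 1 (768) and bortezomib 2 (622), and rose without knockout-labelled bortezomib 3 (2820). It was 2524 with DESeq2, 4862 with limma voom, 2319 without a filter and 4015 without the 3 libraries. With the Xist share as a covariate, added after seeing the data, it was 276, and calls ended for 13 named genes, Cycs (adjusted p = 0.0513) among them. Over the 1462 genes the fold kept a median of 94.3% (quartiles 84.4% and 105%), 0 changed direction and standard errors had a median of 1.14 times their size. With length and GC offsets the camera direction of the ribosomal list turned (median -0.28, adjusted p = 0.518), the glycolysis median was -0.35 and the endothelial call ended (0.107).

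In the reporter mice, RFP single positive HSCs were compared with double positive HSCs to ask how cells with different reporter fluorescence differ in untreated marrow. Markers of monocytes and neutrophils and transcripts of ribosomal proteins and mitochondria lay lower in single positive cells by camera. Monocyte, macrophage and dendritic markers had 0 of 16 members passing, 4 lower adjusted over the list alone (median -0.39, camera adjusted p = 0.000626, adjusted p = 0.668 with an estimated correlation). Neutrophil and granule markers had 0 of 10, with 1 higher and 2 lower adjusted over the list alone (median -1.05, camera adjusted p = 0.0433, adjusted p = 0.672 with an estimated correlation). Ribosomal proteins had 0 of 76, also 0 adjusted over the list alone (median -0.16, camera adjusted p = 0.000626, adjusted p = 0.912 with an estimated correlation). Mitochondrial transcripts had 0 of 13, also 0 adjusted over the list alone (median -0.27, camera adjusted p = 0.0401, adjusted p = 0.912 with an estimated correlation). The complement gene C1qa stood at 5.74 ± 2.58 against 17.4 ± 2.02 CPM, S100a8, a neutrophil alarmin, at 4.73 ± 0.625 against 12.8 ± 2.94, and the abundant myeloid genes Lyz2 and Cst3 at 595 ± 75.4 against 625 ± 91.8 and 519 ± 79.3 against 587 ± 88.9.

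All 4 of these list calls depended on libraries. Without single positive 2, the ribosomal (median -0.017, adjusted p = 0.757), mitochondrial (-0.16, 0.274), neutrophil (0.229) and monocyte (0.0588) calls ended. Others that ended were mitochondrial without single positive 3 (0.0534), ribosomal without double positive 1 (-0.068, 0.421) or 2 (-0.066, 0.464), and neutrophil without double positive 1 (0.0579), 2 (0.117) or 3 (0.186). Medians moved without single positive 1 for ribosomal (-0.39) and mitochondrial lists (-0.43), single positive 3 for neutrophil (-1.65) and monocyte lists (-1.52), double positive 1 for mitochondrial (-0.045, camera direction reversed, adjusted p = 0.830) and monocyte lists (-0.81), and double positive 3 for ribosomal (-0.34) and mitochondrial lists (-0.43).

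Between single and double positive cells edgeR called 0 of 15375 genes, with 209 at an unadjusted p under 0.05; DESeq2 called 2 and limma voom 0. Within the limits for ranked genes the smallest p, besides those of C1qa and S100a8, included those of the Notch ligand relative Dlk1 (11.7 ± 3.49 against 2.78 ± 0.123 CPM) and Fkbp14 (3.75 ± 0.362 against 11.1 ± 2.91). Median and mean or test differed in sign for heat shock, ATF4, NRF2, HSC identity, oxidative phosphorylation, NF-kB and endothelial lists. With length and GC offsets the ribosomal (adjusted p = 0.908) and neutrophil (0.243) calls ended, as did the neutrophil and mitochondrial calls without a filter (both 0.0718), and the mitochondrial list turned with the offsets (median -0.048, 0.399). In simulated data of this design 14.9% of 2-fold and 63.9% of 4-fold changes were recovered.

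RFP single positive HSCs were also compared with double negative HSCs. HSC identity genes lay higher in single positive cells, with 0 of 33 passing and 1 adjusted over the list alone. Their median was 0.38 (camera adjusted p = 1.44e-06, adjusted p = 0.624 with an estimated correlation). Vwf, the von Willebrand factor gene (ENSMUSG00000001930.17, chromosome 6, 125546774 to 125686679), stood at 83.9 ± 3.67 against 23.2 ± 4.37 CPM (log2 fold change 1.85, SE 0.24, edgeR adjusted p = 0.0601), and Kit at 714 ± 100.1 against 482 ± 359. Proteasome subunits lay lower (0 of 36 passing, also 0 adjusted over the list alone, median -0.41, camera adjusted p = 3.96e-08, adjusted p = 0.692 with an estimated correlation). So did oxidative phosphorylation (0 of 45, also 0 adjusted over the list alone, median -0.33, camera adjusted p = 3.96e-08, adjusted p = 0.692 with an estimated correlation) and ribosomal proteins (0 of 76, also 0 adjusted over the list alone, median -0.34, camera adjusted p = 1.69e-08, adjusted p = 0.692 with an estimated correlation). Mitochondrial transcripts were called lower as well (0 of 13, also 0 adjusted over the list alone, median -0.37, camera adjusted p = 0.0239, adjusted p = 0.692 with an estimated correlation). Neutrophil markers (0 of 10, 2 lower adjusted over the list alone, median -1.001, camera adjusted p = 0.00102, adjusted p = 0.624 with an estimated correlation) and monocyte markers (0 of 16, also 0 adjusted over the list alone, median -0.32, camera adjusted p = 0.0239, adjusted p = 0.624 with an estimated correlation) were lower too. Psma7 stood at 699 ± 114 against 1149.6 ± 458 CPM and Psmb1 at 536 ± 76.8 against 789 ± 197.

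Without double negative 1, the library apart on the first component, the ribosomal (median -0.087, adjusted p = 0.0944), mitochondrial (-0.18, 0.393) and monocyte (-0.17, 0.0883) calls ended and the oxidative phosphorylation median was -0.21. The mitochondrial call also ended without single positive 2 (0.127) or double negative 3 (0.165), and the monocyte call without single positive 2 (-0.50, 0.106) or double negative 2 (0.0835). Medians moved without single positive 1 for ribosomal (-0.53), neutrophil (-1.97) and monocyte lists (-0.54), single positive 2 for ribosomal (-0.18) and neutrophil lists (-1.65), single positive 3 for neutrophil (-1.86) and monocyte lists (-0.48), double negative 2 for the proteasome (-0.19) and double negative 3 for monocyte markers (-0.78). The monocyte median was -0.53 without a filter. No list call of this comparison held with length and GC offsets. The proteasome (adjusted p = 0.548), HSC identity (0.122), neutrophil (0.345) and monocyte (0.548) calls ended. The camera direction turned for oxidative phosphorylation (median -0.11, 0.345), ribosomal proteins (-0.10, 0.0669) and mitochondrial transcripts, which passed as higher (0.29, 5.21e-06).

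Single positive against double negative gave 0 of 15375 genes by edgeR (1160 at an unadjusted p under 0.05). DESeq2 called 35, limma voom 0, and edgeR 6 without a filter and 2 with the replicate block (1989 at an unadjusted p under 0.05). After Vwf, the smallest p included those of the Wnt modulator Sfrp1 (16.5 ± 1.62 against 4.75 ± 1.65 CPM), Tns2 (60.7 ± 11.1 against 18.1 ± 10.2) and S100a8 (4.73 ± 0.625 against 19.1 ± 7.87). Leaving out double negative 3 gave 6 genes. Median and mean or test differed in sign for heat shock, cell cycle, megakaryocyte and T and NK cell lists.

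Double positive HSCs were compared with double negative HSCs. Vwf rose from 23.2 ± 4.37 to 94.1 ± 26.0 CPM (log2 fold change 2.02, SE 0.24, edgeR adjusted p = 0.0251), with every double positive library above every double negative library. It was the only gene that passed of 15375, with 1315 at an unadjusted p under 0.05, while DESeq2 called 94 genes, limma voom 0 and edgeR without a filter 8. The call ended without double positive 2 (adjusted p = 0.145), double positive 3 (0.0999), double negative 1 (0.140) or double negative 2 (0.296), which left 0 genes, and with limma voom (0.0761), length and GC offsets (0.508) or only the groups compared (0.264), and leaving out double negative 3 gave 7. HSC identity genes lay higher in double positive cells, with 1 of 33 passing, also 1 adjusted over the list alone. Their median was 0.42 (camera adjusted p = 2.22e-06, adjusted p = 0.763 with an estimated correlation). Lower in double positive cells were proteasome subunits (0 of 36, or 1 adjusted over the list alone, median -0.47, camera adjusted p = 2.47e-10, adjusted p = 0.763 with an estimated correlation). Oxidative phosphorylation (0 of 45, also 0 adjusted over the list alone, median -0.32, camera adjusted p = 6.38e-08, adjusted p = 0.763 with an estimated correlation) was lower, as were ribosomal proteins (0 of 76, also 0 adjusted over the list alone, median -0.16, camera adjusted p = 0.00797, adjusted p = 0.839 with an estimated correlation).

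Among members of these lists, Psma7 stood at 692 ± 101 in double positive against 1149.6 ± 458 CPM in double negative cells, Psmb1 at 561 ± 118 against 789 ± 197, Kit at 783 ± 248 against 482 ± 359 and Atp5b, a subunit of ATP synthase, at 1941 ± 229.7 against 2222 ± 185. After Vwf the smallest p included those of Sfrp1 (14.9 ± 1.47 against 4.75 ± 1.65), Tmcc3 (5.22 ± 3.39 against 0.0994 ± 0.172) and cyclin E2 (Ccne2, 39.3 ± 2.21 against 102 ± 49.1), all with edgeR adjusted p = 0.555. Without double negative 1 the oxidative phosphorylation median was -0.20, and without double negative 2 the HSC identity median was 0.26. The ribosomal call turned in direction and ended without double positive 3 (adjusted p = 0.859) or double negative 1 (0.556). Its median was -0.26 without double positive 1, -0.26 without 2 and -0.0009 without 3, and 0.08 without double negative 1, -0.28 without 2 and -0.26 without 3. With length and GC offsets the oxidative phosphorylation call ended (median -0.17, adjusted p = 0.676). The ribosomal list then passed in the opposite camera direction (median -0.028, adjusted p = 0.0129). Median and mean or test differed in sign for heat shock, interferon, glycolysis and immediate early lists.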

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

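Of the tests in this part, the length and GC offsets, the Xist covariate (with libraries left out too), the omission of 3 libraries and the progenitor test were chosen only after the result was seen. Values of the next 3 paragraphs come from a test of the interaction, and positive ones mean a more positive bortezomib effect in knockout-labelled HSCs.

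The interaction passed for 1462 genes. List medians were 0.42 (core autophagy), 0.40 (lysosome), 0.85 (interferon), -1.49 (cell cycle), 0.47 (HSC identity), -0.96 (oxidative phosphorylation), -0.18 (glycolysis), -0.60 (ribosomal proteins), 1.30 (immediate early genes), 1.46 (NF-kB targets) and 2.33 (endothelial and stromal markers). All 11 passed camera with the preset correlation and none with an estimated one (adjusted p from 0.389 to 0.588). Library dependence is given above. Of 100 splits drawn from 200, keeping group sizes, 9 gave as many genes as the real one. The highest other (4183) swapped genotype labels in a treatment and sums genotype effects over both. All 9 divided bortezomib libraries by genotype, as did 10 drawn, and splits that mixed them gave 0 genes. The rule set beforehand reads 9 of 100 as chance. But the 10 share the genotype difference under bortezomib, so the test cannot decide.

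Among genes, interaction log2 fold changes were 5.74 for Pcdhb16, 5.17 for Fam46c, -4.14 for Hbb-bt, -3.46 for Sdc1, -3.37 for Bok and -3.05 for Ccne1. In protein quality control they were 2.34 (Sqstm1), -1.32 (Phb2), 1.08 (Gabarapl1), 1.64 (Rb1cc1), 1.14 (Gaa) and 1.23 (Cln3). In stress responses they were 2.76 (Me1), 2.77 (Osgin1) and 2.61 (Ppp1r15a). In metabolism and the cell cycle they were -2.08 (Cycs), -1.73 (Cox5a), -1.30 (Tpi1), -2.14 (Mcm5) and -2.01 (E2f1). Inflammatory and early genes gave 2.42 (Rsad2), 2.19 (Gbp2), 3.20 (Cxcl10), 1.92 (Birc3), 1.98 (Klf6) and 2.13 (Ier3). HSC identity genes gave 1.55 (Tek) and 1.51 (Krt18), and the progenitor marker Cd48 gave -2.78. Gpr18, near 0 in a group, passed at an adjusted p of 0.0112, and its fitted fold moved by over 1.5 times without WT bortezomib 3 (adjusted p = 0.00448).

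Calls of 7 more genes ended without single libraries, with the adjusted p given for each. Nol3 (adjusted p = 0.0230) lost its call without WT DMSO 1 (0.0656), WT bortezomib 1 (0.0536), knockout-labelled DMSO 1 (0.0563) and 2 (0.0630) and bortezomib 2 (0.0502), and Kif1a (0.0199) without WT DMSO 2 (0.0528) and knockout-labelled DMSO 1 (0.0585) and 2 (0.0662). Psmd3 (1.05) lost it without knockout-labelled DMSO 2 (0.0505). Rad51c (-3.48) lost it without WT DMSO 1, 2 and 3 (0.0904, 0.0935, 0.0618), WT bortezomib 1, 2 and 3 (0.104, 0.0670, 0.0612), knockout-labelled DMSO 1 and 2 (0.114, 0.105) and bortezomib 2 (0.102). Without WT DMSO 1 and 2, WT bortezomib 1 and 2, knockout-labelled DMSO 2 and bortezomib 1, in that order, the adjusted p was 0.0671, 0.0790, 0.0709, 0.0572, 0.0808 and 0.0634 for Rpl27 (-1.12), 0.0640, 0.0679, 0.0790, 0.0565, 0.0795 and 0.0645 for Psmg1 (-1.28), and 0.0738, 0.0807, 0.0787, 0.0625, 0.0908 and 0.0852 for Col1a2 (2.26). It was 0.0727 (Psmg1) and 0.0580 (Col1a2) without knockout-labelled DMSO 1, and 0.0606 (Rpl27) without bortezomib 2. The Xist covariate ended the calls of Nol3, Kif1a, Ccne1, Cycs, Rpl27, Gbp2, Rb1cc1, Gaa, Cln3, Tpi1, Psmd3, Psmg1 and Col1a2 (adjusted p from 0.0513 to 0.191), and length and GC offsets that of Psmg1 (0.0502).

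Oxidative phosphorylation and ribosomal protein genes were called higher in WT bortezomib than in WT DMSO by camera with the preset correlation (39 of 45 and 20 of 76 passing), but not with an estimated one (adjusted p = 0.565 and 0.642). A trend with transcript length and GC content may contribute. With offsets for both, 52.6% of the oxidative phosphorylation median stayed (51.0% to 59.9% with libraries left out; adjusted p = 0.00704, but 0.107 without WT DMSO 3 and 0.0661 without WT bortezomib 2), and 38.2% of the ribosomal median, whose call ended. The bound written beforehand asked for over 50% and an adjusted p under 0.05; it did not say that this p must hold without each library, which was required after the values were seen, so the trend cannot be told apart. Progenitors in the gate are open too: their markers had a median of -0.15 (-0.27 to -0.12 with libraries left out), below the bound of 0, but their quartiles of -0.44 and 0.20 lie on both sides of 0, and the bound was tightened for that reason after the value was seen. A response to bortezomib stays open as a hypothesis.

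No gene was called between the genotypes in DMSO by edgeR (1454 at an unadjusted p under 0.05; DESeq2 178, limma voom 114, edgeR without a filter 189 and with length and GC offsets 15), against 5234 under bortezomib. Libraries apart on the third component stay open. Without them the DMSO count rose to 40, under the bound of 50, but only WT DMSO 3 was dropped there, leaving fewer libraries. With the Xist share as a covariate 5218 genes were called under bortezomib, 99.7% of the count without it and over the bound of 0.67, but 44.2% (1699 of 3842) without knockout-labelled bortezomib 1, the only one of its group with a share above 3.51%. So 1 library carries this test (98.5% to 115% without another). In DMSO, with 2 genes, the shares do not overlap, so sex make-up cannot be told apart. A genotype difference during proteasome inhibition stays open as a hypothesis.

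Proteasome and oxidative phosphorylation genes were called lower in double positive than in double negative reporter cells by camera with the preset correlation. No member passed (0 of 36 and 0 of 45), and neither call held with an estimated one (adjusted p = 0.763 for both). Double negative 1 as the whole cause is argued against by medians of -0.47 (proteasome) and -0.20 (oxidative phosphorylation, adjusted p = 0.00123) without it. With length and GC offsets 79.3% of the proteasome median stayed (adjusted p = 0.0129; 37.4% and up to 0.737 with a library left out) and 53.6% of the oxidative phosphorylation median, whose call ended (adjusted p = 0.676), so this trend cannot be told apart. A biological difference between the sorted populations stays open as a hypothesis.

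For the 7 pairwise comparisons, the 10 splits of 6 libraries are too few for a share under 0.05. Real and highest other counts were 2508 and 0 (WT bortezomib against DMSO, 1 split as large), 586 and 1 (knockout-labelled, 1 split), 5234 and 0 (genotype under bortezomib, 1 split) and 1 and 0 (double positive against double negative, 1 split). For genotype in DMSO and the other 2 reporter comparisons, edgeR gave 0 genes in all 10 splits (unadjusted p under 0.05 for 1454, 209 and 1160 in the real ones; DESeq2 178, 2 and 35; limma voom 114, 0 and 0).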

How the results depend on the processing

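The length and GC offsets, the Xist covariate and the omission of 3 libraries together were chosen only after the results were seen. No call of a named gene changed direction in any setting. The cause was not tested for the changes below, except where fewer libraries or genes enter the fit. All 63 list calls ended with an estimated correlation, and fry ended 34 and added 6. Relative log expression size factors ended no call and added 1 list.

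Without a filter on low counts, edgeR called 1085 genes (bortezomib in knockout-labelled HSCs), 189 (genotype in DMSO), 2319 (interaction), 6 (single positive against double negative) and 8 (double positive against double negative). DESeq2 called 1283, 178, 2524, 35 and 94 in the same comparisons and 2 between single and double positive cells. Limma voom called 6234 (bortezomib in WT), 1577 (bortezomib in knockout-labelled HSCs), 114 (genotype in DMSO), 4862 (interaction) and 0 (double positive against double negative; edgeR 1, 1315 at an unadjusted p under 0.05). With only the libraries of the groups compared, counts were 318 (bortezomib in knockout-labelled HSCs), 23 (genotype in DMSO) and 0 (double positive against double negative). Length and GC offsets gave 15 for genotype in DMSO and 0 for double positive against double negative. With the Xist share as a covariate, counts were 1629 (bortezomib in WT), 2 (genotype in DMSO) and 276 (interaction). Without the 3 libraries they were 3961, 40 and 4015 in these comparisons and 1902 for bortezomib in knockout-labelled HSCs. This omission ended 8 list calls and 1 named gene call and added 4 and 10, and the Xist covariate ended 21 named gene calls.

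Leaving out 1 library gave 588 to 2762 genes for bortezomib in WT, 182 to 1040 in knockout-labelled HSCs, 0 to 1 for genotype in DMSO, 3582 to 6000 for genotype under bortezomib, 352 to 2820 for the interaction, 0 to 0 for single against double positive, 0 to 6 for single positive against double negative and 0 to 7 for double positive against double negative. Where an arm kept 2 libraries, the spread was pooled over the groups of the fit.

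With the replicate number as a block, counts were 23 for genotype in DMSO and 2 for single positive against double negative, and no other count moved by over 1.5 times. The block added calls for 9 named genes and for cell cycle genes (single against double positive) and progenitor markers (single positive against double negative). It ended those of neutrophil markers (single against double positive, adjusted p = 0.1203) and glycolysis (interaction, 0.0665). The monocyte median of single against double positive was -0.21, and the neutrophil median of single positive against double negative -1.87. The labels do not pair the numbers. Same-number pairs correlated above 0.1 in 8 of 18 (treatment) and 7 of 9 (reporter). Best matches shared the number for 9 of 12 and 8 of 9 libraries. Pairs averaged r = 0.109 and 0.225 (other numbers -0.051 and -0.111), so both sets may be paired.

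Camera changed direction for some lists. With length and GC offsets the medians were then, for ribosomal proteins, 0.20 (bortezomib in WT), -0.13 (genotype under bortezomib), -0.28 (interaction), -0.10 (single positive against double negative) and -0.028 (double positive against double negative). They were -0.048, 0.29 and 0.34 for mitochondrial transcripts in the 3 reporter comparisons, -0.064 and 0.22 for the proteasome between genotypes in DMSO and under bortezomib, and 0.0019 and -0.11 for oxidative phosphorylation between genotypes in DMSO and in single positive against double negative cells. The mitochondrial median of single against double positive ranged from -0.43 to -0.045, the latter without double positive 1, and the ribosomal median of double positive against double negative was -0.0009 without double positive 3 and 0.080 without double negative 1. Among these, the offsets also gave calls not made without them for the proteasome under bortezomib, oxidative phosphorylation in DMSO (adjusted p = 0.0425) and mitochondrial transcripts of double positive against double negative (0.000233).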

Other observations

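All tests in this part were planned before the result was seen, and no hypothesis is added. Vwf, called between reporter populations, also differed in the treatment experiment. It stood at 36.3 ± 3.91 CPM in WT DMSO, 32.8 ± 3.41 in WT bortezomib, 65.7 ± 12.3 in knockout-labelled DMSO and 28.7 ± 7.94 in knockout-labelled bortezomib libraries, and fell with bortezomib in knockout-labelled HSCs (log2 fold change -1.20, SE 0.22, edgeR adjusted p = 0.00619). This call ended without knockout-labelled DMSO 2 (adjusted p = 0.0516).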
